A study of Mus musculus with 4 samples.

How the data were processed

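RNA sequencing was analysed for 4 libraries of mouse embryonic stem cells, 1 per group. The groups, taken from the sample labels, were wild type (WT, the E14 line), cells labelled SO, an Ldha knockout (Ldha_KO) and an Ldhb knockout (Ldhb_KO). The series text describes an inhibitor treatment beside the knockouts. The labels do not spell out SO, and its dose and duration are not given in the sources used here. Per the labels' protocols the cells were grown in serum with LIF on gelatin and polyadenylated RNA was sequenced.

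Per the submitters' processing notes, the mouse build was mm9 and the tools included Bowtie2 2.3.4.3, SAMtools 1.9, HTSeq 0.11.2 and edgeR 3.26.8. The role of each tool and the gene annotation are not given in the sources used here. The deposited tables hold 1 value for each of 25170 gene symbols, and these were read as FPKM (fragment counts scaled by transcript length and library depth) made by the authors. That reading came from the values alone, which are not whole numbers, sum to a different total in each library and step by amounts that differ between genes. RPKM and FPKM could not be told apart, and the depth in reads is not given in the sources used here.

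The design fixed before the data were examined assumed read counts. It named a fallback for normalized values, which was used: the difference of log2(FPKM + 1) between 2 libraries, with a pseudocount of 1, over genes with a value of at least 1 in at least 1 library. This kept 13142 genes. A gene was called higher or lower when the difference reached 1 on this scale, which is 2-fold. Such differences understate the change of genes with low values. With 1 library per group there was no replicate check, no p-value and no error on any value, and every difference compares libraries, not conditions.

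Relative depth was estimated from low values. Among genes below 0.2 in both libraries, the value worth 1 read in SO was 0.956 of that in WT, in Ldha_KO 1.00 and in Ldhb_KO 0.951, which puts the depths at 1.05, 0.995 and 1.05 times WT. Of the ratios of such genes to WT, 63.3%, 53.1% and 60.9% lay within 0.2% of a ratio of small whole numbers of reads, against 0.948%, 0.771% and 0.442% when the step was moved by 5%. For genes with a single annotated transcript the steps pointed most often to a depth of 12000000 to 13000000 fragments in WT (17 of 96 genes), where 1 fragment on a transcript of 1 kb would be worth 0.080. This is a rough figure from another annotation, so no counting interval was computed.

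The same steps separated the libraries. WT and SO shared the value of 1 read to within 0.0169% (the span from the 10th to the 90th percentile over 352 genes). The spans of WT with Ldha_KO and Ldhb_KO were 0.614% and 0.459%, those of SO were 0.657% and 0.475%, and that between the knockouts was 0.225%. By these spans WT and SO fall on 1 side. Ldha_KO and Ldhb_KO were placed together on the other, less surely, since their span is far wider than that of WT with SO. The ratio also moved with the size of the step, with rank correlations of 0.46 to 0.53 in size over all pairs, and this does not separate the sides. The labels name no batch. The comparisons of SO with WT and of Ldha_KO with Ldhb_KO stay on a side, and those of either knockout with WT cross the split.

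There were 28 gene lists, with 730 entries fixed before the data were examined, of which 728 were found by symbol or by a synonym in the RefSeq table of GRCm38.p6. A list's median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart in the lowest or highest 2.5%, which describes these libraries and is not a p-value. Lists with fewer than 8 kept members got no percentile. Chromosome medians used the assignment of GRCm38.p6, and no coordinates were used because the builds differ. Genes named in the text were Ldha, Ldhb, Ldhc and Hdac1, the 10 highest and 10 lowest genes per comparison with at least 5 in the higher library, and up to 4 members of each list that stood apart or held a called gene. Zscan4 members, Dux, Zfp352, Tcstv1, Tcstv3, Pou5f1, Sox2, Nanog, Klf4, Esrrb and Zfp42 were always included. Other genes named were chosen after their values were seen.

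The calls were tested on simulated data for SO against WT over 13142 genes. Changed genes were drawn from those with at least 5 in WT, and the noise was multiplicative, without the counting noise of low values. The rates of the rule below therefore do not cover genes at low values, such as the Zscan4 members in WT. With an assumed noise of 0.1 (SD of the natural log), the rule recovered 4% of genes changed 1.5-fold, 48% of those changed 2-fold and 100% of those changed 3-fold or 4-fold, and called 0 unchanged genes higher. With a noise of 0.2 it recovered 40% at 2-fold and 98% at 3-fold and called 42 unchanged genes higher. Of 100 random lists of 20 genes, 2% stood apart, and all did after a shift of 0.5. Random lists do not show how often lists of genes that vary together stand apart. Alternatives were another pseudocount, other filters, rescaled libraries and other fold limits. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.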

Results

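Transcripts were measured in 4 libraries of mouse embryonic stem cells: wild type, cells labelled SO (an inhibitor treatment in the series text), an Ldha knockout and an Ldhb knockout. The study asks how lactate dehydrogenase and lactylation of Hdac1 relate to the 2-cell state, the transcriptional programme of the 2-cell embryo that appears in a small share of cultured stem cells. Each group had 1 library, so differences have no replicate check and compare libraries, not conditions. The deposited values summed to 526316 in WT, 471595 in SO, 477538 in Ldha_KO and 484528 in Ldhb_KO, and 11952, 12376, 12396 and 12577 genes reached 1. Levels below are FPKM, and differences are on the log2(FPKM + 1) scale. Of the 27 gene lists with a percentile, 11 stood apart higher and 5 lower in SO against WT. The counts were 12 and 2 in Ldha_KO and 13 and 5 in Ldhb_KO. Random lists would give 0.675 each way, so standing apart was common among these lists.

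The targeted genes followed the labels. Ldha, which encodes the A subunit of lactate dehydrogenase, was at 1774 in WT, 1711 in SO, 154 in Ldha_KO and 2237 in Ldhb_KO. Ldhb, which encodes the B subunit, was at 76.5 in WT, 139 in SO, 158 in Ldha_KO and 5.74 in Ldhb_KO. Ldhb was thus 2.06-fold higher in Ldha_KO than in WT, and its difference of 0.86 in SO lay below the 2-fold rule. With libraries rescaled to the summed value of WT, the difference in SO was 1.02, which passed the rule. Ldhc, the testis form, was at 1.24, 2.58, 4.60 and 3.11 in the same order. Hdac1, a histone deacetylase, was at 56.1, 49.4, 42.0 and 44.7. Pseudogenes of Ldha can take or lend reads, so the remaining level in Ldha_KO is uncertain.

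**Figure D1:**
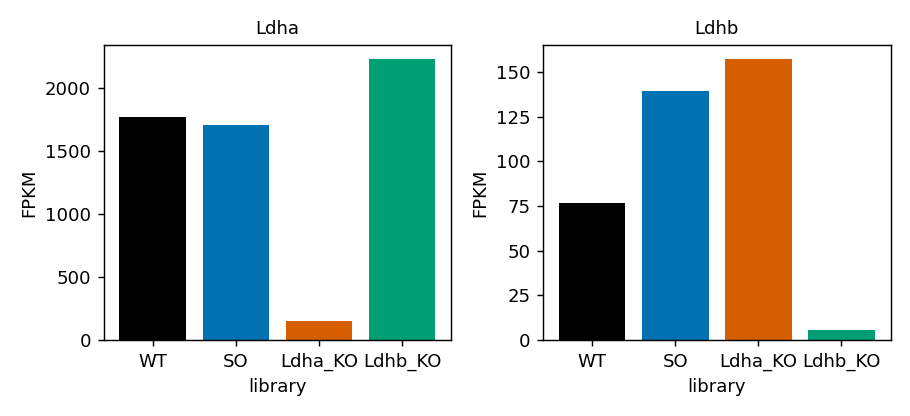
Bars give the FPKM of Ldha (left) and Ldhb (right) in each library, 1 library per group. Ldha is at 154 in Ldha_KO and Ldhb at 5.74 in Ldhb_KO.

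In SO against WT, 2-cell-like genes were higher. Of 46 members found, 30 were kept, of which 21 were higher and 0 lower. The median difference of the kept members was 1.77, which lay above all random lists. Some members passed the filter only through SO or Ldha_KO, as BB287469 at 0.234 in WT, 0.355 in Ldhb_KO and 3.97 in SO. The filter thus favours members high in these libraries. Gm5662 was at 29.1 in SO and 2.21 in WT, Gm2022 at 12.3 and 0.952, Gm2016 at 25.5 and 2.91 and Gm8300 at 22.0 and 2.77. Zscan4c and Zscan4d, members of the Zscan4 family linked to telomere maintenance, were at 16.9 and 14.5 in SO and at 2.03 and 1.72 in WT. Zscan4a was at 9.28 and 0.781, Zscan4f at 6.75 and 1.04, Zscan4b at 2.62 and 0.299, and Tcstv3 at 7.52 and 1.45. Dux, a transcription factor that activates this programme, was listed at 0 in WT and at 0.161 in SO, Tcstv1 was listed at 0 and at 0.232, and Zfp352 was at 0.186 and 1.67. In every library Dux and Tcstv1 lay below the filter of 1. With 1 fragment on a transcript of 1 kb worth about 0.080, their values may rest on few fragments. Most of the 2-cell-like genes named here belong to families of near-identical copies that share reads, so the value of each copy is uncertain.

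**Figure D2:**
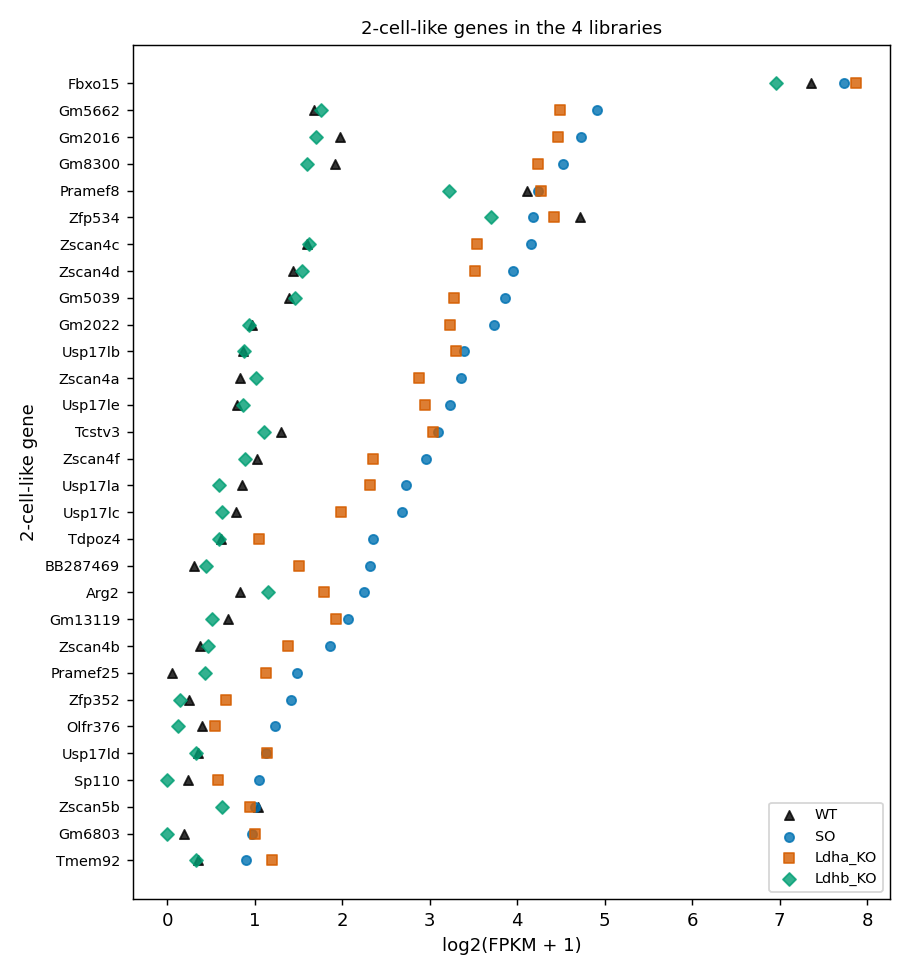
Each line is a kept 2-cell-like gene and each point its log2(FPKM + 1) in 1 library. SO (circles) and Ldha_KO (squares) lie to the right of WT (triangles) and Ldhb_KO (diamonds) for most genes, as for Gm5662 at 29.1, 21.4, 2.21 and 2.37.

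In the same comparison, p53 targets were higher, with 11 of 25 called, 0 lower and a median of 0.59. Plk2 was at 45.9 in SO and 6.89 in WT, Btg2, an antiproliferative gene, at 59.4 and 12.2, Trp53inp1 at 102 and 24.1, and Perp at 49.8 and 11.6. Hypoxia genes had a median of 0.69 with 7 of 22 higher and 0 lower. The collagen prolyl hydroxylase subunit P4ha2 was at 24.0 and 4.63, Ddit4, an inhibitor of mTORC1, at 114 and 28.1, Ndrg1 at 32.6 and 9.93 and Ankrd37 at 20.3 and 7.20. Glycolysis genes had a median of 0.34, and 1 of 20, Aldoc, was called (15.1 and 6.41). Trophectoderm genes had a median of 0.45, with Krt19 at 32.2 and 6.38. Collagen IV genes of the endoderm list, Col4a1 (23.8 and 6.67) and Col4a2 (7.23 and 1.89), were higher, and the list's median was 0.26, which was no longer apart with a filter of 5 (0.13) or with the summed value of WT (0.35). Germline genes had a median of 0.22, with Taf7l at 14.4 and 5.19 and Tex101 at 9.53 and 3.67.

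Lists that stood apart lower in SO than WT were amino acid starvation genes (median -0.35, 2 of 30 lower and 1 higher), cell cycle genes (-0.32), neuroectoderm genes (-0.34, 1 of 9 lower and 1 higher), replication-dependent histones (-0.33) and imprinted genes (-0.19). Chac1, a glutathione-degrading enzyme induced by Atf4, was at 4.07 in SO and 17.1 in WT, Nupr1 at 5.91 and 15.7, and the serine synthesis enzyme Psat1 at 111 and 221. Ddit4, the member with the largest difference, was higher (114 and 28.1). Of the neuroectoderm genes, Gbx2 was lower and Neurod1 (8.06 and 1.56) higher. Of the imprinted genes, Sgce (5.51 and 1.24) and Peg10 (99.0 and 47.6) were higher and Phlda2 (34.6 and 94.2) was lower. No cell cycle gene was called, with Ccne1 at 114 and 208. Histone genes are near-identical copies, mostly without poly(A) tails, and are uncertain. Genes with the lowest differences also included Fgf17 (3.15 and 18.3), the Nodal antagonist Lefty1 (5.48 and 26), Gbx2 (6.85 and 27.7) and Lef1 (2.46 and 9.51), the last a transcription factor of Wnt signalling. The highest also included the protease inhibitor Serpine2 (80.8 and 11.5), Anxa8 (7.19 and 0.138), and Gm21761 (73.7 and 11.1). Serpine2 and Anxa8 also lay 2-fold or more above WT in both knockouts. Snora74a was listed at 0 in WT and at 27.5 in SO. Pou5f1 was at 1115 and 1330.1, Sox2 at 344 and 371, Nanog at 541 and 503, Klf4 at 133 and 124, Esrrb at 207 and 240 and Zfp42 at 523 and 624, and the pluripotency list did not stand apart (median -0.25).

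By the rule, 353 genes were higher and 62 lower in SO than in WT. With a pseudocount of 0.1 the counts were 808 and 182. The call of imprinted genes ended in 4 of 5 alternatives, with percentiles of 3.02 under that pseudocount, 6.91 without the filter, 13.6 with a filter of 5 and 2.83 with libraries rescaled to the summed value of WT. The median of immediate early genes, 0.12 and apart with 1 of 19 higher and 1 lower, was -0.02 without the filter.

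In Ldha_KO against WT, 2-cell-like genes were also higher, 18 of 30 with 0 lower and a median of 1.2. Gm5662 was at 21.4 in Ldha_KO, Gm2016 at 21.1, Gm8300 at 17.8 and the deubiquitinase gene Usp17lb at 8.83, against 0.815 in WT for the last. Zscan4c was at 10.6, Zscan4d at 10.5, Zscan4a at 6.35, Zscan4f at 4.10, Zscan4b at 1.60, Tcstv3 at 7.23, Zfp352 at 0.597, Tcstv1 at 0.369 and Dux at 0.254. Immediate early genes went both ways, with 8 higher and 4 lower of 19 and a median of 0.47. The AP-1 subunits Fos (80.2, WT 4.3), Fosb (18.5, WT 0.190) and Jun (16.9, WT 2.08) were higher. The growth regulator Myc (12.7, WT 66.5) was lower.

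Imprinted genes, expressed from 1 parental copy, were higher in Ldha_KO, 7 of 24 with 0 lower and a median of 0.47. Rian was at 20.5 (WT 4.65), Mest at 47.1 (WT 13.6), Plagl1 at 4.93 (WT 0.713) and Sgce, which was also higher in SO, at 6.73 (WT 1.24). Germline genes had a median of 0.68 with 6 of 19 higher, among them Dazl, an RNA-binding protein of germ cells (51.1, WT 13.0), Tex101 (16.7, WT 3.67), Taf7l (19.5, WT 5.19) and Asz1 (2.68, WT 0.201). The p53 list had 8 of 25 higher and a median of 0.44, with Plk2 at 64.5, Trp53inp1 at 79.8, the cell cycle inhibitor Cdkn1a at 130 (WT 46.6) and Eda2r at 51.6 (WT 18.2). Hypoxia genes had a median of 0.37 with 4 of 22 higher, including P4ha1 (41.5, WT 14.5) and Loxl2 (12.3, WT 4.05), and glycolysis genes a median of 0.18. In the Nrf2 list, median 0.04, Hmox1 (190, WT 83.0) and Gclc (61.1, WT 27.3), the enzymes of heme breakdown and glutathione synthesis, were higher. Endoderm genes had a median of 0.38 with 4 of 16 higher. Amino acid starvation genes also stood apart upwards, at a median of 0.10, with 1 of 30 higher, Atf3 (14.1, WT 2.47), and 1 lower, Chac1 (2.34, WT 17.1).

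Pluripotency genes stood apart lower in Ldha_KO, with 7 of 32 lower, 0 higher and a median of -0.41, as did formative and primed genes with 4 of 17 and -0.51. Gbx2 was at 4.16 (WT 27.7), Socs3, a feedback inhibitor of LIF signalling, at 16.0 (WT 76.3), Lefty2 at 23.1 (WT 74.4), Otx2 at 25.3 (WT 61.6) and Pou3f1 at 3.2 (WT 8.09). The core factors were at 972 for Pou5f1, 204 for Sox2, 591 for Nanog, 193 for Klf4, 220 for Esrrb and 526 for Zfp42. The inhibitors of FGF signalling Spry4 (15.6, WT 111) and Spry2 (17.8, WT 72.1) and the growth factor Fgf15 (3.67, WT 19.5) were among the lowest. Stra8, a meiotic entry gene, was at 31 (WT 2.71), and also lay 2-fold or more above WT in SO (9.41) and Ldhb_KO (14.8). Xlr3c was at 13.6 (WT 1.12) and Osr2 at 9.66, listed at 0 in WT.

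By the rule, 348 genes were higher and 139 lower in Ldha_KO than in WT, and 868 and 321 with a pseudocount of 0.1. The higher genes made up 71.5% of those called, and 83.3% when libraries were rescaled to the summed value of WT.

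In Ldhb_KO against WT, hypoxia genes were higher, 12 of 22 with 1 lower and a median of 1.15, and glycolysis genes had a median of 0.51 with 3 of 20 higher. Ddit4 was at 213 (WT 28.1), the hormone gene Adm at 9.25 (WT 1.44), Loxl2 at 19.2 (WT 4.05) and the glucose transporter Slc2a1 at 690 (WT 307). Amino acid starvation genes were higher, 8 of 30 with 0 lower and a median of 0.69. Ddit3, a transcription factor of the stress response, was at 98.3 (WT 15.6), Nupr1 at 62.6 (WT 15.7) and Aldh1l2 at 3.45 (WT 0.809). The other highest genes included Ndufa4l2 (134, WT 22.0) and Cox4i2 (18.2, WT 2.57), both mitochondrial, the carbonic anhydrase Car12 (7.75, WT 0.454), Anxa2 (110, WT 24.5) and Krt19 (34.1, WT 6.38). Each of these also lay 2-fold or more above WT in SO and Ldha_KO, as Ndufa4l2 at 95.2 and 103. Amd1 was at 8.31 (WT 0.028) while its near-identical copy Amd2 was at 38.4 (WT 61.4), so their values are uncertain.

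The 2-cell-like genes were not higher in Ldhb_KO, with 0 of 30 higher, 1 lower and a median of -0.07. Zscan4c was at 2.06, Zscan4d at 1.92, Zscan4a at 1.02, Zscan4f at 0.856, Zscan4b at 0.379, Gm5662 at 2.37, Tcstv3 at 1.16, Zfp352 at 0.106 and Tcstv1 at 0.116, and Dux was listed at 0. The member called lower, Zfp534, was at 12.0 (WT 25.3). This median lay near 0 and yet low among random lists (percentile 1.02), whose own median was 0.18, and not with a filter of 5 (4.74). Imprinted genes had a median of 0.28 with 6 of 24 higher, led by the noncoding RNAs H19 (28.7, WT 1.65), Rian (20.6, WT 4.65) and Meg3 (14, WT 3.51). Germline genes had a median of 0.62 and interferon genes 0.48, with 3 of 16 higher and 0 lower. Tap1, a peptide transporter of antigen presentation, was at 5.15 (WT 0.965), and was also higher in SO (6.59) and Ldha_KO (3.27). In Ldha_KO 5 interferon genes were higher and 2 lower, and the list did not stand apart (median 0.03). Trophectoderm genes had a median of 0.45 (0.17 and no longer apart without the filter) and p53 targets 0.27. Immediate early genes had 0.27 (1 of 19 higher, Ier3, and 1 lower, Myc), cholesterol synthesis genes 0.20 and adhesion genes 0.15.

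Lower lists in Ldhb_KO were formative and primed genes (median -0.45, with Foxd3 at 5.54 and WT at 18.9), 2-cell regulators (-0.35, none called), cell cycle genes (-0.34) and pluripotency genes (-0.33). Dppa3, a pluripotency list member of the early germline, was higher (10.3, WT 4.03). Pou5f1 was at 1084, Sox2 at 389, Nanog at 424, Klf4 at 142, Esrrb at 248 and Zfp42 at 500. After Ldhb itself, the genes with the lowest differences included Mid1 (5.95, WT 37.0), 2210409E12Rik (3.73, WT 20.3), Myc (14.8, WT 66.5), Exoc3l (9.01, WT 40.4), Lefty2 (21.1, WT 74.4) and Erdr1 (0.832, WT 5.08). By the rule, 441 genes were higher and 143 lower, and 1141 and 311 with a pseudocount of 0.1. The higher share was 75.5%, and 86.4% when rescaled to the summed value of WT.

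Ldha_KO and Ldhb_KO were placed, less surely than WT and SO, on the same side of the split in the value of 1 read. Between them, 18 of 30 2-cell-like genes were higher in Ldha_KO, 0 were lower and the median was 1.21. The p53 targets had a median of 0.31 (2 of 25 higher and 1 lower) and the Nrf2 list 0.14, which without the filter was 0.08 and no longer apart. Lower in Ldha_KO were amino acid starvation genes (median -0.59, 7 of 30 lower and 1 higher), hypoxia genes (-0.58), glycolysis genes (-0.32), cholesterol synthesis genes (-0.24) and immediate early genes (-0.20). Immediate early genes had 6 members higher and 4 lower, and the list's median was 0.14 without the filter. Socs3 was at 16.0 and 125, Ier3 at 7.44 and 61.9, Ddit3 at 21.0 and 98.3, Chac1 at 2.34 and 42.4, and Dppa3 at 0.952 and 10.3. Fos was at 80.2 and 8.70 and Mid1 at 65.7 and 5.95. By the rule 219 genes were higher and 202 lower, and 419 and 574 with a pseudocount of 0.1.

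**Figure D3:**
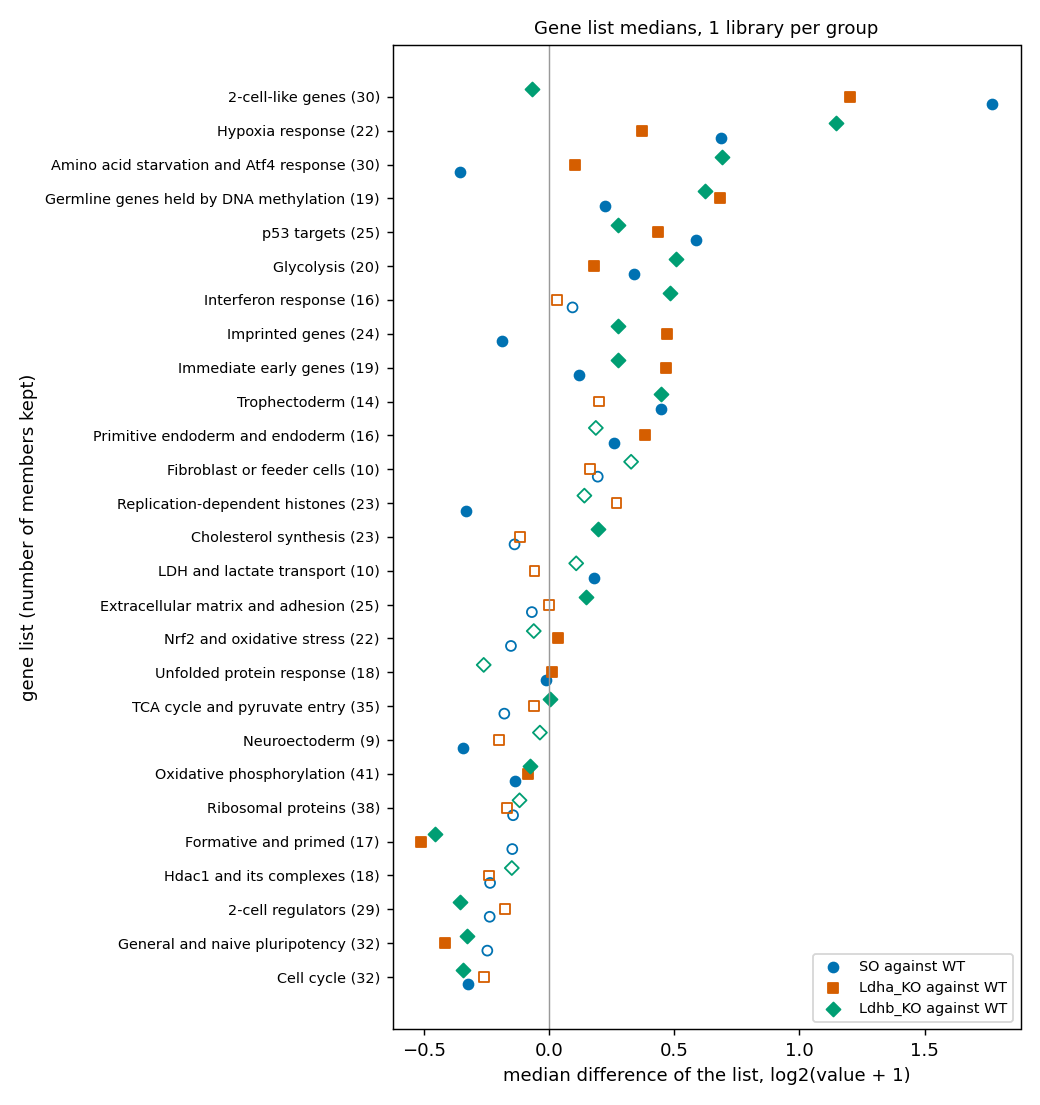
Each point is the median difference from WT of a gene list on the log2(FPKM + 1) scale, filled when it lay in the lowest or highest 2.5% of random lists. The 2-cell-like genes lie at 1.77 in SO, 1.2 in Ldha_KO and -0.07 in Ldhb_KO.

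Hdac1 and its complexes had medians of -0.23, -0.24 and -0.15 in SO, Ldha_KO and Ldhb_KO against WT, with 0 of 18 members called in each. Ribosomal protein genes had medians of -0.14, -0.17 and -0.12, with 1 of 38 called, Rps27 in Ldha_KO. Fibroblast or feeder genes, which test for another cell type, had medians of 0.20, 0.17 and 0.33 and did not stand apart, with 1, 0 and 2 of 10 higher and Pdgfrb at 0.949 in WT and 3.35, 2.80 and 3.63. Oxidative phosphorylation genes had medians of -0.14, -0.08 and -0.08, with 0 of 41 called, yet stood apart upwards because random lists matched on expression had lower medians. These signs turned to 0.02, 0.06 and 0.04 when libraries were rescaled to the summed value of WT. Unfolded protein response genes stood apart upwards with medians of -0.01 in SO and 0.01 in Ldha_KO, and the TCA cycle list with 0.01 in Ldhb_KO. None of these had a member higher, and Herpud1 was lower in Ldha_KO (10.4, WT 22.0). With the summed value of WT the unfolded protein response calls ended in SO (percentile 97.3) and in Ldha_KO (97.4). The call in Ldha_KO also ended without the filter (97.2), and the TCA cycle median turned to -0.0048 with a filter of 5. The list of lactate dehydrogenase and lactate transport genes stood apart with 0.18 in SO, with 0 of 10 members called. Its largest differences were -0.89 for Emb, 0.86 for Ldhb and 0.67 for Ldhc, and 6 members lay above 0 and 4 below. Only 7 mesoderm genes were kept, with medians of 0.53, 0.02 and -0.14 and no percentile.

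The comparisons with WT shared genes. Of the genes higher than WT, 151 were so in both SO and Ldha_KO, 100 in SO and Ldhb_KO and 118 in both knockouts, against 9.35, 11.8 and 11.7 for independent lists, and 60 were higher in all 3. Independent lists leave out the shared WT library: simulated unchanged libraries that share a control had 41.7 higher genes and 3 in common at an assumed noise of 0.2, and 0 of each at 0.1. Across 13142 genes, which are not independent replicates, the differences correlated with r of 0.64, 0.51 and 0.56 in that order, against 0.50 in simulated unchanged libraries that share a control. The covariances were 0.126, 0.107 and 0.125, against 0.015 and 0.060 for assumed noise of 0.1 and 0.2. The simulated noise was multiplicative, without counting noise. The simulated covariances and overlaps follow its assumed size, so they do not bound what unchanged libraries would give. The single WT library cannot be split, and part of the excess may come from it. Between comparisons that share no library, r was 0.01 for SO against Ldhb_KO with Ldha_KO against WT, 0.10 for SO against WT with Ldha_KO against Ldhb_KO and -0.10 for SO against Ldha_KO with Ldhb_KO against WT. As rank correlations these were -0.057, a change of sign, 0.0047 and -0.064, and the first was 0.026 with a pseudocount of 0.1, 0.00417 without the filter and 0.037 and 0.058 with filters of 5 and 10. Genes higher in both numbered 61, 47 and 12, against 5.43, 5.88 and 3.29 for independent lists, and 38, 10 and 44 genes were called in opposite directions. The first and last pairs set a difference across the split in the value of 1 read against its reverse. A shift between the sides would lower their r, and only the second pair stays within sides. The covariances were 0.0014, 0.020 and -0.018, the first being the sum of the others, so these are not separate checks.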

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

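All tests of explanations in this part were chosen after the results were seen. The differences between groups below were not tested, since each group has 1 library.

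Genes called in opposite directions against WT are given with the gap between their differences. The stress genes were Chac1, higher in Ldhb_KO and lower in Ldha_KO (gap 3.70), and Nupr1, higher in Ldhb_KO and lower in SO (3.2). Ier3 (2.90) and Dppa3 (2.53) were higher in Ldhb_KO and lower in Ldha_KO, and the histone gene H3c3 (2.59) was higher in Ldhb_KO and lower in SO. Mup6 (2.33) and Esp24 (2.26) were higher in SO and lower in Ldhb_KO at values below 10. Ldhb had a gap of 4.56 between the knockouts, in one of which it was targeted. Lists that stood apart in opposite directions were 2-cell-like genes (gap 1.84 between SO and Ldhb_KO), amino acid starvation genes (1.04 between Ldhb_KO and SO, with Ldha_KO also apart higher at a median of 0.10) and imprinted genes (0.66 between Ldha_KO and SO). The first rests on the call in Ldhb_KO, where the median was -0.07 against 0.18 for random lists, and which ended with a filter of 5. The last rests on the call in SO, which ended with a pseudocount of 0.1, without a filter, with a filter of 5 and with the summed value of WT.

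The 2-cell-like genes were higher in SO and Ldha_KO than in WT. A WT library out of place would raise them in Ldhb_KO as well, where the median was -0.068. A split of WT with SO from both knockouts would leave the libraries of a side alike. The medians within the sides were 1.77 for SO against WT and 1.21 for Ldha_KO against Ldhb_KO. The knockouts shared the value of 1 read less sharply (span 0.225%) than WT and SO (0.0169%), so a difference in preparation between the knockouts stays open. Reads moved among copies would leave a family's sum unchanged, and of the 5 families with several listed members the sum over every gene of the family in SO and Ldha_KO was at least 5.65-fold that of WT for Zscan4, 7.08-fold for Usp17l and 5.23-fold for Tcstv. For Tdpoz (3.09-fold, from a sum of 0.80 in WT), Pramef (1.23-fold) and the other members it stays open, since the sum over the list, in which Fbxo15 alone made up 162 of the 229 in WT, was 1.86-fold in Ldha_KO, short of the 2-fold set to exclude it. An effect of the inhibitor and of Ldha loss, and a chance difference in the share of 2-cell-like cells between dishes, cannot be told apart with 1 library per group.

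The imprinted list had medians of 0.47 and 0.28 in Ldha_KO and Ldhb_KO and -0.19 in SO, where Sgce and Peg10 were nevertheless higher than in WT. In all, 25 genes separated both knockouts from WT and SO by 2-fold or more, 20 higher, with 5 of the 10 Xlr genes among them, and 5 lower. Scaling would move all genes of a library alike, yet the imprinted list lay at or above percentile 99.35 of matched lists in both knockouts, and the median of all genes in a knockout against WT or SO was at most -0.0021, where scaling that gives 2-fold needs 1. The split in the value of 1 read coincides with the knockouts, so a difference in library preparation cannot be told apart from the knockouts. Derivation through single cells is also open, with the imprinted median of 0.47 in Ldha_KO and no clone without a deletion among the libraries.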

How the results depend on the processing

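The pseudocount of 0.1, the run without a filter and Spearman's rho were planned, and the filters at 5 and 10, both rescalings, the 1.5-fold and 4-fold limits and Ldhb_KO as reference were chosen after seeing the data. The planned scalings, prior counts, counting intervals, thinning and count simulations need read counts and were not run, because normalized values were used. No paired analysis was possible because each group has 1 library, and no library could be left out of a group. Of 360 values of named genes 316 kept their call under every alternative that gave a value, and 0 reversed. Of 108 list medians 91 did. A filter does not change a gene's difference. The 360 gene values without a filter and the 312 with a filter of 5 therefore kept their calls by construction. Many named genes were also picked for large differences in these same libraries, which favours kept calls. Genes or lists that a stricter filter removed gave no value. The cause of the moves below was not tested, except that other fold limits and filters change the number of genes by construction.

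Counts of higher and lower genes for SO, Ldha_KO and Ldhb_KO against WT and for Ldha_KO against Ldhb_KO moved as follows. With a pseudocount of 0.1 they were 808 and 182, 868 and 321, 1141 and 311, and 419 and 574. At 1.5-fold they were 1088 and 564, 1175 and 829, 1652 and 946, and 856 and 1063. At 4-fold they were 39 and 4, 29 and 7, 16 and 5, and 21 and 12. With a filter of 5, SO had 234 and 40 and Ldhb_KO 262 higher. The other counts stayed within 1.5 times. Those without a filter did so by construction, since a gene below 1 in every library cannot reach a difference of 1. Rescaling to the summed value of WT moved the median of all genes from -0.04, -0.03 and -0.02 to 0.10, 0.09 and 0.08, and the difference of Ldhb in SO to 1.02. Overlaps moved by over 1.5 times in 20 of 42 values and divisions of the libraries in 45 of 98.

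The 2-cell-like medians of SO and Ldha_KO stood apart under every alternative, Ldhb_KO as reference included. In Ldhb_KO that list had -0.14 with a filter of 5 and no longer stood apart. Imprinted genes in SO no longer did with a pseudocount of 0.1 (-0.19), no filter (-0.090), a filter of 5 (-0.19) and the summed value (-0.033). Immediate early genes in SO were at -0.021 without a filter, a change of sign, and no longer apart at 0.050 with a filter of 5 and 0.24 with the summed value. In Ldha_KO against Ldhb_KO their sign changed to 0.14 without a filter and 0.23 with a filter of 5. Without a filter, trophectoderm in Ldhb_KO (0.17), the unfolded protein response in Ldha_KO (0.012) and the Nrf2 list between the knockouts (0.08) no longer stood apart, and formative genes in SO did (-0.18). With a filter of 5, formative genes in SO (-0.35) and trophectoderm in Ldha_KO (0.31) stood apart. So did the list of lactate dehydrogenase and lactate transport genes, which holds both targeted genes, in Ldhb_KO (0.084) and between the knockouts (-0.22). With that filter endoderm in SO no longer stood apart (0.13), and the TCA list in Ldhb_KO changed sign (-0.0048). With the summed value, oxidative phosphorylation changed sign to 0.021, 0.055 and 0.041, and the unfolded protein response in SO to 0.14. The latter was 0.048 with the median ratio. Endoderm in SO (0.35) and the unfolded protein response in SO (0.14) and in Ldha_KO (0.15) no longer stood apart with the summed value.

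Correlations of SO with Ldha_KO were 0.66 with a pseudocount of 0.1, 0.63 without a filter, 0.65 with a filter of 5, 0.60 as rho, 0.62 with the summed value and 0.63 with the median ratio. For SO with Ldhb_KO they were 0.52 with the pseudocount, 0.50 and 0.48 with filters of 5 and 10, 0.54 as rho and 0.49 and 0.50 when rescaled. For both knockouts they were 0.58, 0.54 and 0.52, and 0.54 and 0.55 when rescaled. Of the comparisons that share no library, SO against Ldhb_KO with Ldha_KO against WT gave 0.026 with the pseudocount, 0.00417 without a filter, 0.037 and 0.058 with filters of 5 and 10, and reversed to -0.057 as rho. SO against WT with Ldha_KO against Ldhb_KO gave 0.13, 0.13, 0.15, 0.0047 as rho, and 0.11 with either rescaling. SO against Ldha_KO with Ldhb_KO against WT gave -0.093 with a filter of 5 and -0.064 as rho. The largest distance of a chromosome's median from that of all genes, 0.067, 0.088 and 0.073 in the main setting, was 0.097 in Ldha_KO and 0.082 in Ldhb_KO with the pseudocount, 0.023, 0.038 and 0.029 without a filter, 0.075, 0.069 and 0.082 with a filter of 5, 0.085 in Ldha_KO with the summed value and 0.060 in SO with the median ratio.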

Other observations

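The tests in this part were chosen after the results were seen, except the chromosome medians. Of 10 genes with an Xlr symbol, chosen as a group after their values were seen, 5 separated both knockouts from WT and SO by 2-fold or more. Xlr3a was at 18.1 in Ldha_KO and 19 in Ldhb_KO against 6.38 in WT and 6.71 in SO, Xlr3b at 12.1 and 10.2 against 2.3 and 3.93, Xlr4a at 4.12 and 3.81 against 0.801 and 1.15, Xlr5a at 3.88 and 4.12 against 0.642 and 0.767, and Xlr5b at 4.82 and 4.88 against 0.768 and 0.653. Xlr3c was higher in Ldha_KO than in the others (13.6, with 3.53 in Ldhb_KO), and Xlr, Xlr4b, Xlr4c and Xlr5c were in none of the divisions. These are near-identical copies and their single values are uncertain. The homeobox gene Rhox1, on the X chromosome in the assignment of GRCm38.p6, was at 12.9 and 11.0 against 4.57 and 4.26. Bmp4, a growth factor of early development, was lower in both knockouts, at 20.3 and 20.8 against 58.1 in WT and 54.7 in SO.

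Genes that separated SO and Ldha_KO from WT and Ldhb_KO by 2-fold or more numbered 35 higher and 1 lower, and many were 2-cell-like. Others were the water channel Aqp3 (44.0 in SO, 62.6 in Ldha_KO, 15.4 in WT and 14.8 in Ldhb_KO), the gluconeogenic enzyme Fbp2 (13.8, 13.2, 4.27 and 3.59), the small heat shock protein Cryab (14.5, 11.1, 2.41 and 4.87) and Cd80 (17.4, 10.3, 3.09 and 4.35). The gene that was lower was Chac1. The other divisions into pairs gave 20 higher and 5 lower for both knockouts, and 5 and 0 for SO with Ldhb_KO. Of the divisions of 1 library from the rest, WT gave 9 higher and 60 lower, the most of any division, Ldhb_KO 49 and 15, Ldha_KO 33 and 11 and SO 17 and 10.

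Hypoxia genes were higher in SO, Ldha_KO and Ldhb_KO than in WT. WT lay 2-fold or more below all the others for P4ha1, P4ha2, Loxl2 and Adm of this list. A WT library out of place may therefore account for the rise shared by the others. It would not account for the difference between the knockouts, where the median of Ldha_KO against Ldhb_KO was -0.58, outside the random lists. Random lists do not measure the spread between dishes of 1 group. The split in the value of 1 read would not account for SO against WT, on 1 side of it, with a median of 0.69. A difference in density or oxygen between dishes may still account for the medians, up to 1.15 in Ldhb_KO, and cannot be told apart from the groups with 1 dish each.

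Over 20 chromosomes and 3 comparisons with WT, 16 of 60 chromosome medians lay outside the central range of random gene sets, where chance gives 3. The largest of these differences was 0.080 on chromosome 1 in Ldha_KO. With 3 copies in place of 2 in every cell, the chromosome's WT values would give a median of 0.540 on the same scale. A gain in a part of the cells was not tested. In Ldha_KO against Ldhb_KO, which was not planned here, differences reached 0.106 on the X chromosome and -0.098 on chromosome 15. Some abundant genes with many pseudogenes had low values: Gapdh was at 9.99 in WT and Rps13 at 2.82, while the pseudogene Rps6-ps4 was at 1811. The ribosomal RNA precursor Rn45s was at 489 in WT, 627 in SO, 804 in Ldha_KO and 405 in Ldhb_KO.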
